A study of Aspergillus nidulans with 4 samples.

How the data were processed

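The series holds 4 RNA-seq libraries from mycelium of the filamentous fungus Aspergillus nidulans, strain biA1, which the study uses as its wild type. Each library was made from 1 pool of RNA from 3 cultures. Per the labels' protocols, mycelium grew for 9 to 12 h at 37 °C in minimal medium. Total RNA was depleted of ribosomal RNA, turned into strand-specific libraries with the ScriptSeq kit and sequenced as paired ends on an Illumina HiSeq. The carbon source was 1% glucose, described by the submitters as repressing, or 0.1% fructose, described as non-repressing. The nitrogen source was 10 mM ammonium tartrate, a repressing source, or urea, a non-repressing source. The urea concentration is 10 mM in the sample descriptions and 5 mM in the growth protocol, and which applies was not resolved. Tartrate was present only with ammonium, so each nitrogen comparison is also a comparison of medium with and without tartrate. The carbon comparisons likewise change the amount of sugar together with its kind.

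The authors deposited 8 tables, 1 per comparison and strand. Per the file headers, each gives, for every listed gene, whole-number read counts of 2 libraries, the authors' log2 fold change, a mean log2 CPM, a p-value and an FDR. The submitters' processing notes name HTSeq, a read counter, and edgeR, a package for count statistics, with no version. The aligner, the genome build and the annotation are not given in the sources used here. The names of the deposited tables carry the value 0.3 for the biological coefficient of variation, the spread between cultures that edgeR has to be given when there are no replicates. The deposited p-values and FDR therefore rest on an assumed spread, not a measured one. The deposited FDR equalled the Benjamini-Hochberg adjustment of the deposited p-values in each table. Over all tables, the lowest value of the higher of a gene's 2 libraries was 10.4 CPM, so genes that were low in both libraries are missing from that comparison. The tables also hold 16 columns of normalised values per library, which were not used.

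Sense counts covered 7752 genes in any table, of which 6789 had a count from all 4 libraries, and antisense counts covered 8000. The sense counts of the listed genes summed to 2606076 for glucose with ammonium, 1698692 for glucose with urea, 547041 for fructose with ammonium and 812637 for fructose with urea. These sums are over the listed genes, and the full depth of the libraries is not given in the sources used here. A gene at 0 counts could have had up to 3 counts, which is 1.15 CPM, 1.77 CPM, 5.48 CPM and 3.69 CPM in the libraries in that order. CPM in the text takes the summed counts of the listed genes of the same strand as the total. The counts of a library were identical in its different tables.

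From the deposited counts, a log2 ratio was computed per gene and comparison with TMM scaling (edgeR 4.0.16 in R 4.3.3) and a prior count of 1. Nitrogen ratios are urea over ammonium and carbon ratios are fructose over glucose. For genes with at least 20 counts in both libraries, the ratios lay within 0.0827 of the authors' log2 fold change on every table, after the sign of the deposited nitrogen values, which are ammonium over urea, was turned. Intervals in parentheses after a log2 ratio are exact 95% Clopper-Pearson intervals for the same scaled counts without the prior count. A ratio of a gene with few counts in the lower library is drawn towards 0 by the prior count. A gene at 0 in 1 library is given as at least N-fold higher or lower, against 3 counts. In counts of genes past 4-fold such a gene enters by its ratio with the prior count. Its bound lay below 4-fold for 0, 109, 0 and 56 of the sense genes counted for nitrogen in glucose, nitrogen in fructose, carbon in urea and carbon in ammonium, and for 27, 786, 268 and 413 of the antisense genes. Intervals and floors cover counting error only, since reads from amplified libraries are not independent molecules. With 1 library per condition the differences have no replicate check, no test of the conditions was made, and "higher" and "lower" describe these libraries.

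Genes were counted as different at a ratio of 4-fold or more among genes with a deposited mean log2 CPM of 3 or more. The genes named were fixed by rule before the data were examined: the 10 highest and 10 lowest sense ratios per comparison, up to 4 members with the largest ratio from each list described, the regulators areA, areB, nmrA and creA, the 5 highest and 5 lowest antisense ratios, and the 5 highest and 5 lowest differences between the nitrogen ratios. Not every gene that the rule allows is named, and where a gene outside it is named this is said. The 27 gene lists, covering nitrogen and carbon use, iron, development, secondary metabolism, translation and stress, were fixed at the same time from symbols, an identifier range and words in the deposited gene descriptions, and 35 listed symbols had no match. For lists of 3 or more measured members, the median ratio was placed among the medians of 10000 random lists of the same size, matched on mean abundance in 20 bins. This percentile describes the 2 libraries and does not test the condition. Counts of list members past a size and list medians took all measured members, without the abundance minimum. Applying that minimum to members moved 5 list medians by more than the spread of random lists and left 99 within it. Medians are of ratios with the prior count. They stayed as printed when genes at 0 were set to their bound, except for 3 lists where both values are given.

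The ratios and the size rule were tested on simulated data, Poisson counts for the real genes with 200 genes changed. Of the genes made 8-fold different, 98%, 96%, 99% and 100% passed 4-fold in the sense comparisons of nitrogen in glucose, nitrogen in fructose, carbon in urea and carbon in ammonium. Of the genes made exactly 4-fold different, 49%, 42%, 42% and 48% did. Counting error alone put 0, 21, 0 and 12 unchanged sense genes past 4-fold in the same order, among 6354, 7203, 7135 and 6647 genes. On the antisense strand it put 12, 116, 49 and 129 past it, among 6515, 7248, 7117 and 6723.

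Alternatives fixed before the data were examined were other sizes, other abundance minimums, the deposited FDR, total count and DESeq2 1.42.0 size factors, centring on the median gene, a prior count of 5, and the route through the other 3 tables. Thinning of all libraries to 1 depth, the other scalings of list medians and a ribosomal list without mitochondrial members were added after seeing the data. No reference genome was used, and no coordinates are given. A list of the genes of assembly ASM1142v1, which matched 7345 of the 7752 identifiers, served for gene names and for which genes neighbour each other. Reads shared between near-identical genes cannot be resolved from gene counts. Tables and figures were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.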

Results

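Transcript levels were measured on both strands in 4 libraries of wild-type Aspergillus nidulans, 1 for each combination of glucose or fructose with ammonium tartrate or urea. The design asks how the nitrogen source acts on gene expression under each carbon condition, and how the carbon source acts under each nitrogen condition. Sense counts per library ranged from 547041 for fructose with ammonium to 2606076 for glucose with ammonium, so values from fructose carry the larger counting error. The most abundant listed gene was AN5245, which has no description, in 3 libraries, with 3.31% of sense counts in glucose with urea (95% Clopper-Pearson interval 3.29% to 3.34%). In glucose with ammonium it was AN8746, with 1.23% (1.22% to 1.25%). Both were singled out for their abundance after the values were seen.

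**Figure D1:**
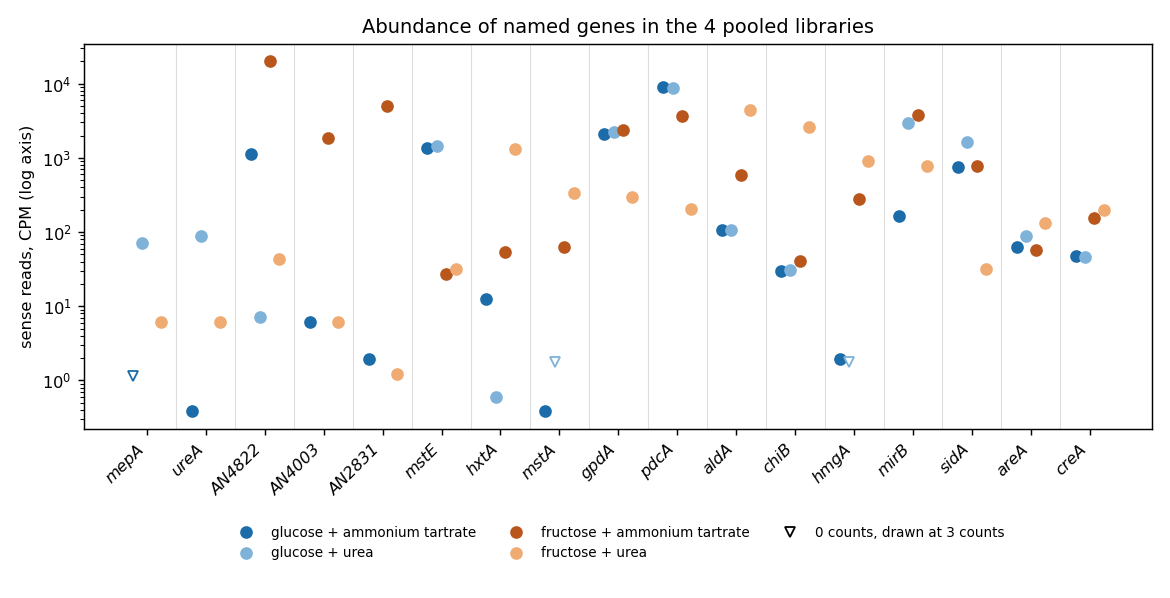
Sense reads of 17 named genes, in CPM on a log axis, with 1 point per pooled library and open triangles for 0 counts drawn at the level of 3 counts. A missing point is a gene not listed for that library. AN4822, a putative tartrate dehydrogenase, stood at 1114 CPM and 19920 CPM in the libraries with ammonium tartrate and at 7.06 CPM and 43.1 CPM in those with urea.

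In glucose, replacing ammonium with urea went with higher transcripts of single transporter genes for ammonium, urea and nitrite and of 4 of 11 siderophore and iron genes, while the lists of glycolysis and ribosomal protein genes differed little. The ammonium transporter gene mepA (AN1181) had 122 counts in urea and 0 in ammonium, at least 64.7-fold higher. The urea transporter gene ureA (AN0418) had 151 counts against 1, a log2 ratio of 6.76 (5.41 to 13.22). A putative asparaginase gene, AN0300, had 163 against 1, with 6.87 (5.52 to 13.33), and the hydrophobin-like gene AN7539 had 348 against 3, with 7.04 (5.97 to 9.81). The tartrate dehydrogenase gene AN4822 had the lowest ratio, with 12 counts in urea and 2904 in ammonium tartrate, -7.16 (-8.20 to -6.44).

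Among 6354 genes past the abundance minimum, 85 were at least 4-fold higher in urea and 34 at least 4-fold lower. Other genes with the highest ratios were ngn26 (AN8539), an ortholog of the siderophore gene sidG of Aspergillus fumigatus, at 5.63 (4.79 to 7.19), AN7322 at 5.17 (4.50 to 6.22), the predicted cell wall protein gene AN7323 at 5.00 (3.88 to 7.78) and AN7990 at 4.21 (3.15 to 6.50). AN8652 and AN1831 also belonged to this group, with 37 and 35 counts against 1. Among the lowest were AN11233, with a predicted chitinase domain, at -4.68 (-10.80 to -2.96), AN7108 at -3.26 (-4.12 to -2.61), AN6729 with 4 counts against 68, and AN3961 at -2.80 (-3.99 to -1.96). AN8490, AN3479, AN8011, AN4949 and AN1550 completed the 10 lowest, each with 3 or fewer counts in urea and between 41 and 59 in ammonium.

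The siderophore and iron list stood out in glucose. Of 11 measured members, 4 were at least 4-fold higher in urea and 0 were 4-fold lower, with a median of 1.17 at the 100th percentile of random lists. The siderophore transporter genes mirB (AN8540) and mirA (AN7800) had ratios of 4.20 (4.06 to 4.35) and 3.07 (2.84 to 3.31). The siderophore biosynthesis gene sidI stood at 2.49 (2.27 to 2.73), and hapX, a regulator of the response to low iron, at 2.38 (1.68 to 3.30). Of 5 genes for the use of urea and arginine, ureA was past 4-fold, the urease gene ureB stood at 1.06 (0.54 to 1.63) and the arginase gene agaA at 0.96 (0.51 to 1.43). The list median was 0.96, at the 99.8th percentile, and 0.38 by the route through the other 3 tables, over the members listed in all 4. Of 6 ammonium assimilation and transport genes, mepA was past 4-fold, the ammonium transporter gene meaA stood at 1.26 (1.09 to 1.43) and the glutamate synthase gene gltA at -1.26 (-1.38 to -1.14). In the nitrate list of 9, the list median was 0.38. Its nitrite transporter gene nitA, which lay below the abundance minimum, had 29 counts against 0, at least 15.4-fold higher.

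All 10 measured glycolysis and fermentation genes lay within 2-fold (median 0.10), as did 74 of 75 genes described as ribosomal proteins (median -0.07) and 37 of 39 chaperone genes (median -0.04). Among the regulators, areA, the GATA factor that activates nitrogen use genes, stood at 0.54 (0.21 to 0.87), areB, another GATA factor, at 0.37 (-0.23 to 0.98), nmrA, a regulator of nitrogen metabolite repression, at -0.61 (-1.17 to -0.09) and the carbon repressor gene creA at 0.02 (-0.41 to 0.44). The authors' deposited table gave an FDR of 0.05 or less to 51 genes higher and 14 lower in urea.

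In fructose, the same change of nitrogen source went with differences in far more genes. In the fixed lists, 7 of 10 glycolysis and fermentation genes, 30 of 74 ribosomal protein genes and 14 of 39 chaperone genes were at least 4-fold lower in urea, while 7 of 16 genes for the use of amino acids and amides and 4 of 9 for ethanol and acetate were at least 4-fold higher. The tartrate dehydrogenase gene AN4822 was again among the lowest, now with a gene of the same description, AN4003. AN4822 had 35 counts in urea and 10897 in ammonium tartrate, a log2 ratio of -9.003 (-9.58 to -8.58), and AN4003 had 5 against 1026, with -8.13 (-10.08 to -7.22). The transporter-like gene AN2831 had 1 count against 2774, with -11.03 (-17.51 to -9.73).

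Among 7203 genes past the minimum, 822 were at least 4-fold higher in urea and 790 at least 4-fold lower, and over genes listed in all 4 tables the numbers were 345 and 684. The 10 highest had 0 to 4 counts in ammonium. They included AN2653, with a predicted monooxygenase domain (617 counts in urea, at least 120-fold higher), the predicted transporter gene AN8084 (353, at least 68.9-fold), the chitin deacetylase gene AN9380 and the cytochrome P450 gene CYP5078A3 (AN7359), each with 157 and at least 30.7-fold. AN7307, AN4077, AN7092 and AN2544 were at least 28.1-fold, 24.0-fold, 20.5-fold and 18.9-fold higher. The beta-glucosidase gene bglF (AN10482) stood at 6.47 (5.05 to 9.97) and the glutaminase gene gtaA (AN4809) at 6.41 (5.29 to 8.53). At the other end, mdhB (AN5031), a putative malate dehydrogenase gene, had 0 counts against 191, at least 109-fold lower, and the adjacent identifier AN5030 stood at -7.97 (-14.45 to -6.66). AN3961 stood at -8.04 (-14.52 to -6.73), AN4127 at -7.89 (-14.37 to -6.58) and AN9297 at -7.80 (-8.72 to -7.21). AN4480 and AN11965 were at least 70.5-fold and 59.2-fold lower.

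Of 10 glycolysis and fermentation genes, 7 were at least 4-fold lower in urea and 0 higher, with a median of -2.90 below all random lists. The genes for phosphofructokinase (pfkA), pyruvate decarboxylase (pdcA), glyceraldehyde-3-phosphate dehydrogenase (gpdA) and phosphoglycerate kinase (pgkA) stood at -4.59 (-4.91 to -4.32), -4.38 (-4.62 to -4.16), -3.22 (-3.43 to -3.03) and -2.99 (-3.20 to -2.79). Of 74 genes described as ribosomal proteins, 30 were at least 4-fold lower and 1 higher (median -1.84, below all random lists). Without the members whose description names mitochondria, a list added after seeing the data, 23 of 41 were 4-fold lower (median -2.27). Of 39 chaperone genes 14 were 4-fold lower and 3 higher (median -1.33, 0.03rd percentile), among them AN3555 at -4.88 (-5.51 to -4.41), AN7892 at -4.44 (-5.11 to -3.95) and hsp30 at -4.02 (-4.55 to -3.60).

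Of 9 ethanol and acetate genes, 4 were at least 4-fold higher and 0 lower (median 1.95, 99.9th percentile), with the alcohol dehydrogenase gene alcB at 4.25 (3.41 to 5.50) and the aldehyde dehydrogenase gene aldA at 2.68 (2.52 to 2.85). Of 16 genes for the use of amino acids and amides, 7 were higher and 1 lower (median 1.61, above 99.9% of random lists, and 0.895 by the route through the other tables), with fahA of phenylalanine breakdown at 5.13 (4.16 to 6.75) and the acetamidase gene amdS at 3.82 (3.22 to 4.59). Of 4 urea and arginine genes, 3 were higher (median 2.61, above 99.8% of random lists), led by the ornithine transaminase gene otaA at 3.42 (3.09 to 3.79) and agaA at 2.91 (2.51 to 3.38). Of 8 genes of extracellular proteolysis and autolysis, 2 were past 4-fold, the chitinase gene chiB at 5.75 (5.20 to 6.48) and the glucanase gene engA at 3.15 (2.88 to 3.46), with a list median of 1.36 at the 98.9th percentile. The ammonium assimilation list had 3 of 5 members 4-fold lower by the ratio with the prior count, glnA for glutamine synthetase at -2.37 (-2.59 to -2.17), gltA at -2.39 (-2.64 to -2.16) and mepB, whose 0 counts against 6 show only that it was at least 3.41-fold lower. The list median was -2.37, or -1.77 with mepB set to its bound.

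The siderophore and iron list had the opposite sign from glucose, with 5 of 11 members 4-fold lower and 0 higher in urea (median -1.47, 1.21st percentile). The ornithine monooxygenase gene sidA stood at -4.75 (-5.45 to -4.25), mirA at -4.52 (-6.09 to -3.65), sidD at -2.67 (-2.88 to -2.47) and mirB at -2.48 (-2.61 to -2.35). Cytochrome P450 genes spread widely, 17 of 43 at least 4-fold higher and 6 lower, with a median of 1.17 over all members that was -0.07 over those listed in all 4 tables by the route through the other tables. Among the regulators, areA stood at 1.03 (0.46 to 1.67), areB at 0.82 with an interval that included 0, nmrA at -0.02 (-0.88 to 0.88) and creA at 0.15 (-0.24 to 0.55). The authors' deposited table gave an FDR of 0.05 or less to 745 genes higher and 856 lower. With a prior count of 5, 1037 genes passed 4-fold in place of 1612.

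**Figure D2:**
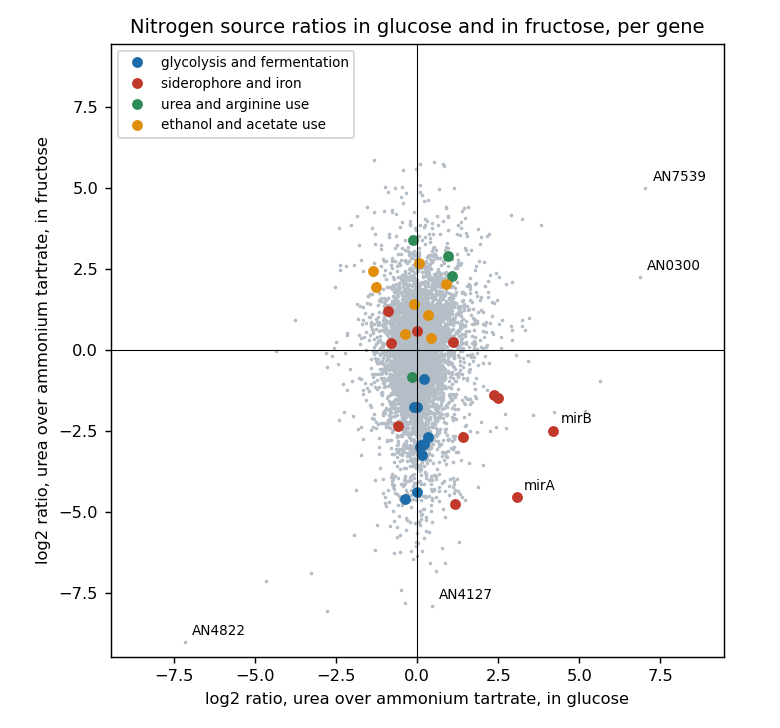
Log2 ratio of urea over ammonium tartrate in glucose (x axis) against that in fructose (y axis) for the 6024 genes past the abundance minimum in both, with 1 point per gene and 4 gene lists in colour. The points spread further along the fructose axis, and mirA and mirB lie at 3.07 and 4.20 on the x axis and at -4.52 and -2.48 on the y axis.

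The 2 nitrogen comparisons share no library. Among 6024 genes past the minimum in both, 65 were at least 4-fold higher in urea in glucose and 382 in fructose, with 14 in both, where independent lists would share 4.12. For genes lower in urea the numbers were 27 and 701, with 5 in both against 3.14 for independent lists. The 14 shared higher genes included AN0300 and AN7539, and the 5 shared lower genes included AN4822, AN11233, AN7108 and AN3961. A further 12 genes passed 4-fold in opposite directions. Across genes, which are not independent replicates, the correlation of the nitrogen ratios was 0.0962 (Pearson) and 0.0869 (Spearman).

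The nitrogen ratio in fructose minus that in glucose was at least 2 on the log2 scale for 429 of the 6024 genes and at most -2 for 750. These genes had to pass the minimum in glucose too, which leaves out genes low in both glucose libraries. Over them, 382 were at least 4-fold higher and 701 lower by nitrogen source in fructose, against 822 and 790 of 7203. The split of 429 and 750 thus holds only for the genes that pass this filter. The most positive differences were those of AN8661 at 7.20, AN8223, described as a carbon starvation response protein, at 6.16 and the carboxypeptidase-like gene AN1426 at 6.02, followed by AN4732 and AN8292, which had 0 counts in fructose with ammonium. AN8661 had 30 and 7 counts in glucose with ammonium and with urea, and 1 and 172 in fructose with ammonium and with urea. The most negative were those of AN4127 at -8.35, mirA at -7.58, AN9297 at -7.42, the sterol isomerase gene AN7211 at -7.42 and AN11574 at -7.39, of which AN7211 and AN11574 had 0 counts in fructose with urea, so their values rest on the prior count. AN4127 had 862, 744, 314 and 1 counts in the same order. These differences are values of 4 single libraries and carry no test.

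With urea as nitrogen source, fructose in place of glucose went with the broadest differences of the 4 comparisons in number of genes past 4-fold. Most listed genes for the use of amino acids, ethanol and acetate and for extracellular proteolysis were higher in fructose, and most listed genes for glycolysis, ribosomal proteins and ammonium assimilation were lower. The catalase-peroxidase gene cpeA (AN7388) had 1756 counts in fructose and 0 in glucose, at least 1016-fold higher, and the arabinanase gene abnC (AN8007) 1711 and 0, at least 990-fold. The homogentisate dioxygenase gene hmgA (AN1897) of phenylalanine breakdown had 747 and 0, at least 432-fold higher. The hexose transporter gene hxtA (AN6923) had 1086 counts against 1, a log2 ratio of 9.70 (8.40 to 16.19).

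Among 7135 genes past the minimum, 1044 were at least 4-fold higher and 1088 at least 4-fold lower in fructose. Over genes listed in all 4 tables the numbers were 428 and 955, and under total count scaling they were 1212 and 920, so the larger direction turned. The lipase gene AN8046 stood at 9.92 (8.77 to 13.67), and AN12477, AN0301, AN2653, AN10588 and AN8611, all at 0 counts in glucose, were at least 382-fold, 359-fold, 357-fold, 332-fold and 293-fold higher. Among the lowest, the sterol isomerase gene AN7211 had 0 counts against 336, at least 64.5-fold lower, and the sterol methyl oxidase gene AN8907 had 43 against 11080, a ratio of -7.19 (-7.68 to -6.78). AN4150, with a predicted role in biotin transport, stood at -7.01 (-9.13 to -5.89), the argininosuccinate synthase gene AN1883 at -6.87 (-8.99 to -5.75), AN4127 at -7.95 (-14.05 to -6.26) and AN3310 at -6.77 (-12.87 to -5.07). AN8495, AN5719, AN0402 and the arrestin-like gene apyA (AN3265), at 0 counts in fructose, were at least 49.5-fold, 47.2-fold, 43.0-fold and 34.4-fold lower.

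Of 8 genes of extracellular proteolysis and autolysis, 6 were at least 4-fold higher (median 4.86, above all random lists), with chiB at 6.09 (5.73 to 6.55), the dipeptidyl peptidase gene dppIV at 5.26 (4.88 to 5.75) and the protease gene prtA at 4.96 (4.55 to 5.49). Of 16 amino acid and amide genes, 10 were higher and 1 lower (median 3.19, above all random lists), with hpdA at 7.94 (7.14 to 9.50), fahA at 7.05 (6.08 to 9.33) and maiA at 6.44 (5.27 to 10.20). Of 9 ethanol and acetate genes 7 were higher (median 3.07, 99.9th percentile), with alcB at 6.70 (5.72 to 8.98) and aldA at 5.08 (4.88 to 5.32). Glycoside hydrolases were 4-fold higher in 29 of 61 cases and lower in 11 (median 1.93), while the fixed polysaccharide degradation list had 3 of 9 higher and 1 lower (median 1.15, 70.5th percentile). Cytochrome P450 genes were higher in 22 of 41 cases and lower in 4 (median 2.16), including CYP548D1 at 9.31 (8.47 to 11.04). Of 6 gluconeogenesis genes 2 were higher and 1 lower (median 1.51, 96.4th percentile): acuF and acuG, for phosphoenolpyruvate carboxykinase and fructose bisphosphatase, at 4.03 (3.78 to 4.32) and 2.98 (2.60 to 3.44), and the enolase gene acuN, also in the glycolysis list, at -3.47 (-3.68 to -3.27). Over the members listed in all 4 tables, by the route through the other tables, the medians of the amino acid, glycoside hydrolase and cytochrome P450 lists were 0.11, 0.18 and 0.0233.

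Of 10 glycolysis and fermentation genes, 9 were at least 4-fold lower (median -3.18, 1.38th percentile), with pdcA at -5.67 (-5.90 to -5.45) and pfkA at -4.47 (-4.78 to -4.19). Of 74 ribosomal protein genes 45 were lower and 0 higher (median -2.99, below all random lists), and the shorter list without mitochondrial members had 33 of 41 (median -4.12). The nitrate assimilation list had 4 of 9 members lower (median -1.79, 1.22nd percentile), among them the nitrate reductase gene niaD at -5.05 (-11.14 to -3.31) and the nitrite reductase gene niiA at -4.36 (-4.87 to -3.94). Of 6 ammonium genes 4 were lower and 1 higher (median -3.07, and -1.83 by the route through the other tables), among them meaA at -5.51 (-6.85 to -4.65) and the glutamate dehydrogenase gene gdhA at -3.86 (-4.14 to -3.60). The urea transporter gene ureA was lower in fructose at -3.94 (-5.76 to -2.87), while otaA and agaA were higher at 4.04 (3.80 to 4.32) and 3.59 (3.29 to 3.94). The sugar transporter genes mstA and mstE diverged. The first had 270 counts in fructose and 0 in glucose, at least 156-fold higher, and the other stood at -5.73 (-6.39 to -5.22). Of the iron genes, mirA stood at -6.13 (-7.59 to -5.22) and sidA at -5.92 (-6.58 to -5.41), with a list median of -1.97 at percentile 2.81.

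Among the regulators, creA was higher in fructose at 1.79 (1.41 to 2.21), and areA, areB and nmrA stood at 0.35 (-0.02 to 0.72), -0.40 (-1.27 to 0.39) and 0.36 (-0.34 to 1.06). The authors' deposited table gave an FDR of 0.05 or less to 1401 genes higher and 1358 lower. With total count scaling the median of all genes past the minimum moved from -0.03 to 0.24.

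With ammonium as nitrogen source, fructose in place of glucose went with fewer differences. In the fixed lists, 6 of 15 genes for the use of amino acids and amides and 14 of 28 polyketide and nonribosomal peptide synthase genes were at least 4-fold higher in fructose, 11 of 75 ribosomal protein genes were lower, and the 10 glycolysis and fermentation genes differed by less than 4-fold. AN2831 had 2774 counts in fructose and 5 in glucose, a log2 ratio of 10.91 (10.10 to 12.95), and the tartrate dehydrogenase gene AN4003 had 1026 against 16, with 8.07 (7.51 to 9.02). AN5030 and mdhB, at 0 counts in glucose, were at least 512-fold and 294-fold higher. The glyceraldehyde-3-phosphate dehydrogenase gene gpdC (AN2583), which is not in that list, stood at 8.61 (7.94 to 9.89).

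Among 6647 genes past the minimum, 554 were at least 4-fold higher and 466 at least 4-fold lower. The larger direction turned at 2-fold, with 1275 and 1505, and over genes listed in all 4 tables, with 278 and 347. AN8781 stood at 8.42 (7.87 to 9.34), and the polyketide synthase gene AN8910, the beta-glucosidase gene bglR (AN9183), AN1553 and AN10891 were at least 186-fold, 136-fold, 131-fold and 112-fold higher. The 10 lowest genes were all at 0 counts in the shallow fructose library, with 87 to 131 counts in glucose and bounds of at least 6.27-fold to 9.45-fold lower. They were AN10771, AN7305, AN2364, AN10915, AN5257, AN12386, AN5684, AN5888, AN7144 and AN4732. Among genes with counts in both libraries, the sugar transporter gene mstE stood at -5.64 (-6.52 to -4.95) and meaA at -4.21 (-5.94 to -3.08).

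Of 15 amino acid and amide genes 6 were at least 4-fold higher and 1 lower (median 1.21, 99.6th percentile, and 0.63 by the route through the other tables), with hpdA at 7.14 (6.12 to 11.07), the proline gene prnD at 6.99 (5.96 to 10.92) and hmgA at 6.73 (5.88 to 8.78). Of 8 proteolysis and autolysis genes 5 were higher (median 2.81, above all random lists, and 2.21 by that route), with dppV at 5.14 (4.64 to 5.86) and dppIV at 4.41 (4.03 to 4.89). Of 28 polyketide and nonribosomal peptide synthase genes 14 were higher and 0 lower (median 1.74, above all random lists, and 0.39 by the route through the other tables). All 3 penicillin cluster genes were higher (94.5th percentile), acvA at 3.62 (2.89 to 4.71), ipnA at 3.08 (1.74 to 5.66) and aatA at 2.18 (1.03 to 3.66). Their counts in fructose and glucose were low, 44 and 15, 10 and 4, and 12 and 11. The iron list had 2 of 11 members higher and 0 lower (median 1.21, 99.8th percentile), mirB at 4.47 (4.32 to 4.63) and sidD at 2.04 (1.91 to 2.17). The heat shock genes AN7892 and hsp30 stood at 4.28 (3.96 to 4.66) and 3.21 (2.98 to 3.47), while the chaperone list as a whole had 5 of 39 higher and a median of -0.18.

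None of 10 glycolysis and fermentation genes was past 4-fold (median -0.37, 44.5th percentile), with pdcA at -1.32 (-1.39 to -1.26). Of 75 ribosomal protein genes 11 were lower and 0 higher (median -1.60, below all random lists), among them AN1166 at -2.54 (-2.75 to -2.34). The regulators creA, areA, areB and nmrA stood at 1.63 (1.23 to 2.06), -0.17 (-0.78 to 0.38), -0.92 (-2.47 to 0.25) and -0.25 (-1.05 to 0.46). The authors' deposited table gave an FDR of 0.05 or less to 686 genes higher and 387 lower.

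**Figure D3:**
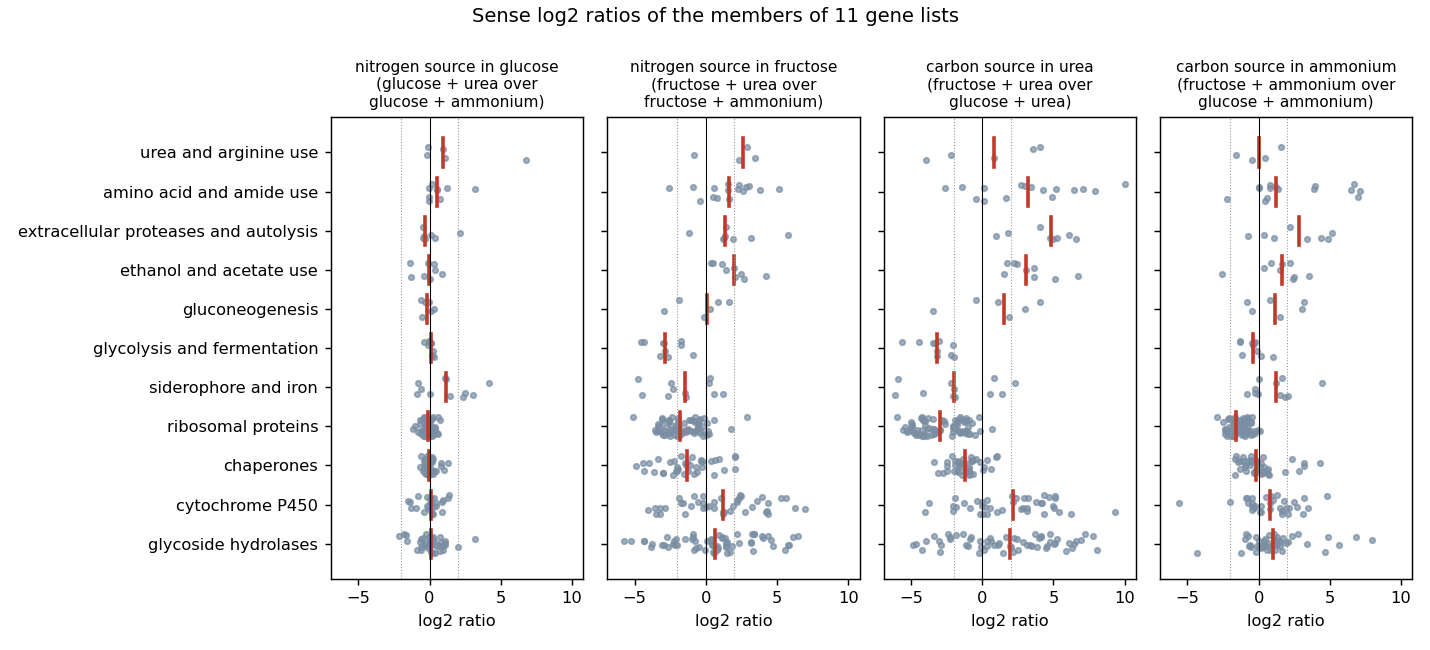
Sense log2 ratios of the measured members of 11 gene lists in the 4 comparisons, with 1 point per gene, a red bar at the median and dotted lines at 4-fold. The glycolysis and fermentation medians lie at 0.10, -2.90, -3.18 and -0.37 from left to right, and the ribosomal protein medians at -0.07, -1.84, -2.99 and -1.60.

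The 2 carbon comparisons also share no library and overlapped more. Among 6400 genes past the minimum in both, 654 were at least 4-fold higher in fructose with urea and 485 with ammonium, with 319 in both against 49.6 for independent lists. For genes lower in fructose the numbers were 1038 and 430, with 149 in both against 69.7. The correlation of the carbon ratios across genes was 0.567 (Pearson) and 0.51 (Spearman). In both comparisons hmgA, hpdA, dppIV, prtA and acuF were higher in fructose and mstE, meaA and gdhA lower.

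Antisense counts made up 28.9% (exact 95% interval 28.8% to 28.9%) of the counts of both strands in glucose with ammonium, 26.6% (26.6% to 26.7%) in glucose with urea, 27.8% (27.7% to 27.9%) in fructose with ammonium and 24.6% (24.5% to 24.6%) in fructose with urea. In glucose, 142 genes had an antisense count at least 4-fold higher in urea and 151 at least 4-fold lower, among 6515. In fructose they were 1184 and 961 among 7248. For carbon in urea they were 1021 and 1270 among 7117, and for carbon in ammonium 629 and 876 among 6723. Over genes listed in all 4 tables the numbers were 82 and 90, 574 and 773, 471 and 1020, and 357 and 640 in the same order. Of the genes counted in fructose by nitrogen source, 786 of 2145 had 0 counts in 1 library and a bound below 4-fold. The authors' deposited table gave an FDR of 0.05 or less to 30 higher and 10 lower antisense genes for nitrogen in glucose, 435 and 549 for nitrogen in fructose, 1010 and 1083 for carbon in urea, and 484 and 323 for carbon in ammonium. The larger direction thus differed from that at 4-fold in 3 comparisons, and for carbon in urea it turned under total count scaling, with 1169 higher and 1126 lower.

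The genes with the largest antisense ratios were often those with the largest sense ratios. In glucose, AN7539 had 245 antisense counts in urea against 0, at least 154-fold higher, with AN3160 at least 44.7-fold and ngn26 at least 15.1-fold higher, and AN7322 and ureA at 6.30 (5.14 to 10.08) and 5.68 (4.34 to 12.20). Antisense AN4822 stood at -6.51 (-8.32 to -5.47). In fructose, antisense counts of chiB were at least 64.9-fold higher in urea, and those of AN2653, AN8084 and the cytochrome P450 gene phacB at least 24.7-fold, 20.8-fold and 16.2-fold. Antisense AN2831 was at least 257-fold lower, and AN4822 stood at -7.72 (-8.56 to -7.14), AN9297 at -8.82 (-15.24 to -7.45) and AN11233 at -7.36 (-9.29 to -6.43). For carbon in urea, antisense AN12341, AN8445, AN0964 and hpdA were at least 307-fold, 250-fold, 205-fold and 144-fold higher, and AN0332, prxA, aspnd1, mirA and AN7211 at least 52.7-fold, 48.8-fold, 33.6-fold, 31.4-fold and 28.5-fold lower. For carbon in ammonium, antisense AN2831 and AN5030 were at least 980-fold and 107-fold higher, and AN4003 and AN8781 stood at 7.47 (6.60 to 9.87) and 7.38 (6.76 to 8.47). The lowest were meaA, AN6904, AN5467, AN10828 and dfgB, at least 14.5-fold, 10.8-fold, 9.52-fold, 9.46-fold and 9.21-fold lower.

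Across genes past the minimum on both strands, the correlation of antisense and sense log2 ratios was 0.412 for nitrogen in glucose (5995 genes), 0.639 for nitrogen in fructose (6534), 0.822 for carbon in urea (6550) and 0.61 for carbon in ammonium (6149). Genes are not independent replicates, and these values describe single pairs of libraries. Among genes with at least 100 counts on both strands together, the median antisense share was 27.6%, 23.4%, 22.8% and 19.2% in glucose with ammonium, glucose with urea, fructose with ammonium and fructose with urea.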

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

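Each of these results was singled out because a list or named gene went in opposite directions under the same contrast, and none of the differences was tested, since each condition is 1 library. The tests of counting error, of scaling and of swapped labels were chosen after the list medians and member counts had been seen. The siderophore and iron list had a median nitrogen ratio of 1.17 in glucose and -1.47 in fructose, a difference of 2.64. Its median carbon ratio was -1.97 in urea and 1.21 in ammonium, a difference of -3.18. Both differences come from the same 4 libraries. For a single gene they are 1 contrast, apart from scaling and sign, so they are not separate results. For the nitrogen ratio, mirA differed by 7.58 between glucose and fructose and mirB by 6.67. For the carbon ratio, mirB differed by -6.65 between urea and ammonium and sidD by -4.07. Outside the iron list, the carbon ratio was below -2 in urea and above 2 in ammonium for AN4480 (difference -7.68), AN9297 (-7.44), AN7322 (-7.04) and the chaperone gene AN3555 (-5.67). AN4480 had 0 counts in fructose with urea and 37 in glucose with urea, so its difference rests on the prior count.

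The iron pattern was set against 3 technical explanations. Counting error alone would leave the intervals of the 2 nitrogen ratios overlapping, but they were apart for 11 of 11 members. Of these, 8 had the lower ratio in fructose, but not all 8 changed sign. The ratio of mirC was 1.12 in glucose and 0.27 in fructose, where its interval included 0. That of cycA was below 0 in both, at -0.59 and -2.33. The other 3, sreA, sidC and acoA, went the other way, and sreA encodes a repressor of siderophore genes. The genes sreA, sidC and cycA lie outside the naming rule and were chosen after the values were seen. The scaling is also argued against, since over the 4 other scalings the median stayed at -1.28 or below in fructose and at 1.12 or above in glucose. A swap of the 2 fructose labels would turn the sign in fructose, but both genes described as tartrate dehydrogenase were lower in the library labelled urea, the medium without tartrate, at -8.13 (-10.08 to -7.22) or below. A difference in iron demand or supply between the media may account for the pattern, as a hypothesis that was not tested, and a difference between these particular pools of cultures stays open.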

How the results depend on the processing

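The size, abundance and prior choices set how many genes count as different, so the numbers in the report depend on them. Values below are for nitrogen in glucose, nitrogen in fructose, carbon in urea and carbon in ammonium, in that order unless named. A 2-fold size gave 728, 3567, 4010 and 2780 sense genes and 1373, 4106, 4240 and 3393 antisense genes, and an 8-fold size 36, 749, 1233 and 456 sense and 96, 833, 1314 and 828 antisense. A minimum mean log2 CPM of 5 gave 36, 890, 1376 and 459 sense and 57, 1050, 1435 and 657 antisense genes, from fewer genes. The deposited FDR gave 65 sense genes for nitrogen in glucose and 40, 984 and 807 antisense genes for both nitrogen comparisons and carbon in ammonium. A prior count of 5 gave 75 and 1037 sense genes for the nitrogen comparisons and 99, 663, 1362 and 837 antisense genes. The route through the other 3 tables gave 1060, 1378 and 589 sense genes for nitrogen in fructose and both carbon comparisons, and 1468 and 916 antisense genes for the carbon comparisons. It needs genes listed in all 4 tables, and over those the direct sense counts were 1029, 1383 and 625, with 33.5% of the genes for nitrogen in fructose higher in urea against 51.0% of all, and 30.9% against 49.0% for carbon in urea. The difference of nitrogen ratios passed 2-fold for 2874 genes and 8-fold for 493. The nitrogen overlap was 189 genes at 2-fold and 9 by the deposited FDR, and the carbon overlap 1516 at 2-fold. The antisense to sense correlation at a minimum of 5 was 0.583, 0.782 and 0.76 for both nitrogen comparisons and carbon in ammonium. For the other changes outside the size and the filters the cause was not tested. Total count scaling, DESeq2 size factors, median centring, no abundance minimum and, added after seeing the data, thinning to the smallest library kept all 8 counts within 1.5 times. Which direction held more genes was less stable and turned under at least 1 alternative in every comparison and strand but nitrogen in glucose, sense, and for the carbon overlap at 2-fold (719 higher, 797 lower). Total count scaling moved the median sense ratio from 0.07 to 0.26 for nitrogen in fructose and from -0.03 to 0.24 for carbon in urea, and the antisense medians of the first 3 comparisons from -0.02, 0.10 and -0.09 to -0.15, 0.22 and 0.13. Of the list medians that stood in the outer 5% of random lists, 3 changed sign by the route through the other tables, also added, over the members listed in all 4: sugar transport for carbon in ammonium (-1.97), and cytochrome P450 (-0.0732) and glycoside hydrolases (-0.19) for nitrogen in fructose. A further 22 list medians moved by more than the spread of random lists by this route and 76 did not. The largest drop among these 22 was that of the amino acid list for carbon in urea, from 3.19 to 0.11. Over the sense genes compared by both routes, no ratio moved by more than 1.07, with a median difference near 0.03. A larger drop cannot come from the route alone and rests at least in part on members not listed in all 4 tables. Of 518 ratios of named genes, a prior count of 5 moved 89 past their counting interval and total count scaling 17, and none past 4-fold changed sign under these. No paired analysis was possible because each condition has 1 library. Depth limits the fructose values most, since 0 counts in fructose with ammonium allow 5.48 CPM.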

Other observations

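Development and secondary metabolism genes also differed between the libraries. Of 4 measured markers of asexual development, 4 were at least 4-fold higher in fructose than in glucose with urea (median 3.73, or 3.08 with brlA, at 0 counts in glucose, set to its bound, and 2.06 by the route through the other tables). Only these 4 of 5 matched markers were listed for that comparison, which leaves out genes low in both libraries, and further symbols of the list had no match. For nitrogen in fructose, 4 of 5 markers were at least 2-fold higher in urea and 1 was at least 2-fold lower. For carbon in urea, the conidiophore pigment gene ivoB stood at 7.41 (6.44 to 9.69), the spore catalase gene catA at 2.95 (2.07 to 4.34) and vosA at 2.11 (1.63 to 2.68). For nitrogen in fructose, ivoB was also higher with urea than with ammonium, at 4.96 (4.14 to 6.21). Of 6 sexual development markers, 2 were 4-fold higher in fructose with urea than in glucose with urea and 2 were 2-fold lower (median 0.96, 91.3rd percentile, and -0.33 by the route through the other tables). Of these, cpeA had 1756 counts in fructose with urea, 155 in fructose with ammonium, 3 in glucose with ammonium and 0 in glucose with urea. For nitrogen in fructose 2 of 6 were higher (median 0.57, 79.6th percentile, and -0.43 by that route), with mutA at 4.57 (3.12 to 8.07). In the sterigmatocystin cluster, taken as an identifier range, 3 of 5 measured members were higher in fructose with urea than in glucose with urea (median 3.74, or 2.80 with the members at 0 set to their bound). The polyketide synthase gene AN12331 had 0 counts in fructose with urea and 52 in fructose with ammonium, at least 29.6-fold lower, and in that comparison 10 of 31 synthase genes were 4-fold lower in urea and 4 higher (median -0.85, 0.91st percentile).

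Among the other lists for the nitrogen source in fructose, some medians lay among those of random lists. Of 9 purine and pyrimidine genes 1 was at least 4-fold higher in urea (median 1.26, 98.2nd percentile), the purine hydroxylase cofactor gene hxB at 2.94. Of 10 nitrogen regulators 2 were higher (median 0.61, 85.8th percentile), xprG at 2.22 (1.47 to 3.19) and prnA at 2.08 (0.78 to 4.23). Of 9 carbon regulators 1 was higher (median 1.10, 97.7th percentile), alcR at 2.99 (2.44 to 3.67). Amino acid transporters went both ways, 1 of 27 higher and 6 lower (median -0.31, 16.0th percentile), with AN3347 at -5.44 (-8.24 to -4.36). Major facilitator transporters had 2 of 10 higher and 1 lower (median 1.28, 98th percentile). The list of genes whose description names histones had 3 of 13 higher and 1 lower (median -0.86, 5.19th percentile). In it AN3926, described for histone methylation, stood at 3.29 (2.34 to 4.76). Polysaccharide degradation genes had 2 of 11 higher and 4 lower (median -0.59, 21.1st percentile), with 3 members at 0 counts in 1 library. The 2 higher ones, abfA and amyB, had 11 and 9 counts in urea against 0, so their bounds lay below 4-fold. Mitochondrial ribosomal proteins had 8 of 37 lower and 0 higher (median -0.94, below all random lists).

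The number of genes that differed by nitrogen source was 119 in glucose and 1612 in fructose. The tests of this pattern were all chosen after ratios of these libraries had been seen. Lower depth in fructose is argued against, since the glucose pair thinned to the fructose totals gave 142 to 175 genes over 20 draws. Noise from few starting molecules was not excluded for all genes. The antisense ratio had the sign of the sense ratio in 88.9% of 1426 genes (exact 95% interval 87.1% to 90.4%), but leaked sense reads would share that noise. Such noise strikes each gene on its own, and of all genes past 4-fold 49.0% were lower in urea. Over genes listed in all 4 tables the split was less even, with 345 higher and 684 lower. Of the 31 ribosomal protein genes past 4-fold, 96.8% were lower (83.3% to 99.9%, an interval that takes genes as independent). These are the 30 lower and 1 higher genes given above, so the value restates that result and is not separate support. It argues against such noise only for the shared direction of this list. A hypothesis that stays open is that fructose with urea left less usable carbon than fructose with ammonium tartrate, where tartrate may have served as a carbon source. The lists do not decide it, since the ethanol and acetate genes lay at the 99.9th percentile of random lists but the gluconeogenesis genes at the 62.3rd (median 0.08, 0 of 6 higher and 1 lower). The lower 1 was the enolase gene acuN, which is also in the glycolysis list. A later growth stage or a difference between pools could give the same.

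The other pattern is that antisense counts followed sense counts. Of its tests, that of neighbouring genes was fixed before its result was seen and that of a uniform share was not. If reads were independent, a single share of reads on the wrong strand for every gene would put about 5% of abundant genes off the library median. Among genes with 1000 or more counts on both strands, at least 77.6% had an exact 95% interval that excluded it, in each of the 4 libraries. Reads from amplified libraries are not independent molecules, which would raise the 5% by an amount that was not measured. A uniform leak of up to the lowest shares, 5.86% at the 1st percentile of abundant genes in glucose with urea, remains possible. Reads from overlapping neighbours would leave isolated genes with little antisense signal, but genes with no neighbour within 500 bases kept a median antisense share of 19.4% or more in each library. Leakage that differs from gene to gene and true antisense transcripts were not separated, so antisense ratios may in part repeat the sense ratios.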
